A study of Drosophila melanogaster with 8 samples.

How the data were processed

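The data are read counts per gene in 8 libraries of total RNA from late pupal fly heads, 150 heads per library. Per the labels' protocols, ribosomal RNA was removed with a RiboMinus kit and libraries were sequenced as SOLiD whole-transcriptome libraries. The authors deposited 1 file per library, and per the submitters' processing notes these counts come from HTSeq and the dm3 genome build. The versions, the aligner, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from a gene and an overlapping or antisense gene can therefore not be told apart, and near-identical copies such as the snoRNA, Eig71E and cuticle protein families may have shared or lost reads. The deposited values are whole numbers whose totals differ between libraries, so they were treated as raw counts per gene, with no normalization by the authors. All 15141 gene symbols are genes, and no summary line entered a library size.

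Groups were taken from the titles: 2 libraries each of the deficiency genotype, the 2-deletion genotype, gain of function and wild type. Symbols were matched to a reference gene table of Release 6, a later assembly than the files use, for current names and gene order only. Of the symbols, 13956 (92.2%) matched 1 gene, and no coordinates are given because the builds differ. GC content was not examined.

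Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and statmod 1.5.0. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and 1 model with 4 group means was fitted to all libraries, leaving 4 residual degrees of freedom. A gene is called at a Benjamini-Hochberg adjusted p of 0.05 from edgeR's robust quasi-likelihood test over the 9252 genes tested. The common biological coefficient of variation was 20.7%. Standard errors of log2 folds are the fold divided by the square root of its F statistic. CPM are TMM-scaled, and log2 CPM use a prior count of 2. For genes with 1 to 3 counts in 1 side of a comparison, the ratio of pooled CPM is given with a 95% exact interval (Clopper-Pearson, from the split of the counts), and for genes with none, a bound against 3 counts over the libraries of that side.

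The 6 comparisons, the tests, 37 gene lists and the rule for named genes were fixed before the data were examined. In the lists, 1 gene was later written by another of its names, which left the members the same. Lists were tested with limma's camera at a preset correlation of 0.01 on log2 CPM, adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives; 35 lists had at least 5 tested members. The lists cover hormone, peptide, neuronal, glial, eye, cuticle, muscle, fat body, immune, stress, metabolic, translation, RNA-binding and other genes, and the report gives each. Named genes were TBPH, EcR and Map205 in loss and gain of function against wild type, and the 7 largest rises and 7 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap of libraries. To these were added the 2 members with the smallest p of each called list, in the direction of the list. The other comparisons took the 4 largest rises and falls, and genes called in both loss and gain the 3 with the smallest product of p-values in each direction. This named 57 genes. Genes named outside the rule are said to be so. For shared calls, 40 draws of unchanged groups were simulated, since the comparisons use the same wild-type libraries. Each gene was drawn independently from its mean over all libraries and its fitted dispersion.

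The gene test was tested on simulated counts with 100 genes changed at each of 2 sizes, in 8 draws. In loss of function against wild type it recovered 25.8% of changes of 1 and 80.5% of changes of 2 on the log2 scale, and 9.67% of calls were on unchanged genes, out of 8921 to 8983 genes run. In gain of function against wild type it recovered 13.8% and 70.6%, with 8.78% of calls on unchanged genes, out of 8947 to 8987. The share of such calls was thus above the 5% that the threshold sets. Changed genes were drawn only from those with a mean log2 CPM of at least 3, so recovery at lower levels was not examined. Every group was simulated with the same dispersion per gene. The replicates of the real groups differ unequally, so these shares may not hold for each comparison. A list given a shift in simulated counts had an adjusted p of 5.72e-11 with the preset correlation and 0.114 with an estimated one. The estimated form can thus miss a shift. Lists whose members vary together were not simulated, so this does not check the preset form for them. In the data the estimated correlation was 0.75 for muscle, 0.42 for cuticle proteins and 0.24 for oxidative phosphorylation. It was lower for other lists, such as 0.0022 for mitochondrial ribosomal proteins and -0.05 for chemosensory genes. Where the correlation is above the preset value, the preset form can give p-values that are too small.

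Alternatives were 11 settings, 1 of which (both genotypes as 1 group) was run only where loss of function was compared with wild type or gain of function, and the removal of each of the 8 libraries in turn. The settings were an adjusted p of 0.01, DESeq2 size factors, upper-quartile scaling, no low-count filter (1 count in all), a filter of 50 counts in 2 libraries, the DESeq2 Wald test, limma-voom, a replicate block, only the libraries of the groups compared, both genotypes as 1 group, and protein-coding genes only. The last was chosen after seeing the data. The labels name no sequencing batch, so no comparison could be made within batches. Depth per library is 716027 to 1302855 counts, which leaves genes of a few counts with the wide intervals given in the report.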

Results

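RNA was measured in heads of late Drosophila melanogaster pupae, 73 to 90 h after puparium formation, with 150 heads pooled per library. The study concerns TDP-43, an RNA-binding protein that forms aggregates in human motor neuron disease and whose fly counterpart is encoded by TBPH. There were 8 libraries in 4 groups of 2. A first loss-of-function genotype carried the deletion allele delta142 over a chromosomal deficiency, and a second carried the deletion alleles delta23 and delta142. These are called the deficiency genotype and the 2-deletion genotype. By their titles, the libraries labelled gain of function expressed the fly protein through an actin 5C driver. Their TBPH counts showed no rise, as given below. The wild-type libraries are given as Canton S and w1118 in their titles and as w1118 in the genotype field, so the exact stock is not settled. Nothing in the labels says that libraries of a group came from separate crosses, so p-values measure the spread between these libraries, which may be technical.

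The total count per library was 858067 and 929745 in the deficiency genotype, 1160738 and 1302855 in the 2-deletion genotype, 1225179 and 1105353 in gain of function, and 868003 and 716027 in wild type. At these depths the floor of 3 counts corresponded to 2.3 to 4.19 CPM (counts scaled to the library total) in single libraries. Counts could be tested for 9252 of the 15141 genes in the files. Spearman correlations of log2 CPM were 0.915 to 0.951 between replicates and 0.861 to 0.912 between wild-type and other libraries. The first principal component held 35.4% of the variance and set the wild-type libraries apart from the other 6, at 42.4 and 46.8 against -24.5 to -1.53. Small RNA genes (snoRNA, snRNA, tRNA and related classes) took 10.4% and 11.8% of the counts in wild type and 11.1% to 15.7% in the others. The replicates of each group differed by more than sampling noise, so no library was counted as a copy of another. Chi-square per degree of freedom was 9.52 in gain of function and 6.08 in the deficiency genotype. It was 3.09 in the 2-deletion genotype and 3.17 in wild type. The model fits a shared dispersion per gene over all groups, so p-values do not measure the spread within each group by itself.

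TBPH, the gene targeted in every mutant genotype, did not pass the test in any comparison. Its counts were 41 and 28 in the deficiency genotype, 47 and 57 in the 2-deletion genotype, 68 and 42 in gain of function, and 43 and 40 in wild type. In normalised values these were 40.1 ± 13.2, 42.2 ± 2.82, 47 ± 11.5 and 53.4 ± 5.23 CPM (mean ± SD, n = 2 each). The log2 fold against wild type was -0.38 in loss of function, with a 95% interval of -0.96 to 0.20 (adjusted p = 0.47, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the libraries labelled gain of function it was -0.18, with an interval of -0.83 to 0.48 (adjusted p = 0.79), whose upper end is a 1.39-fold rise. The labels do not say which part of the gene the deletion alleles remove, and counts outside that part do not check these alleles. If the deficiency removes 1 copy of TBPH, a halving could still be seen in the deficiency genotype. The 95% interval there was -1.1 to 0.267 on the log2 scale, which holds both a halving and no change. TBPH counts therefore did not settle the labels of the loss-of-function libraries. In gain of function the interval leaves out a doubling, so the counts did not bear out that label. A transgene without counted sequence was not tested. Every direction below is that of libraries as labelled.

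EcR, which encodes the ecdysone receptor, was at 413 ± 48.5 CPM in loss of function (SD, n = 4), 437 ± 23 in gain of function and 336 ± 2.97 in wild type (SD, n = 2 each). It did not pass the test in loss of function (log2 fold 0.29, SE 0.14, adjusted p = 0.29) or gain of function (log2 fold 0.38, SE 0.16, adjusted p = 0.23, both edgeR).

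**Figure D1:**
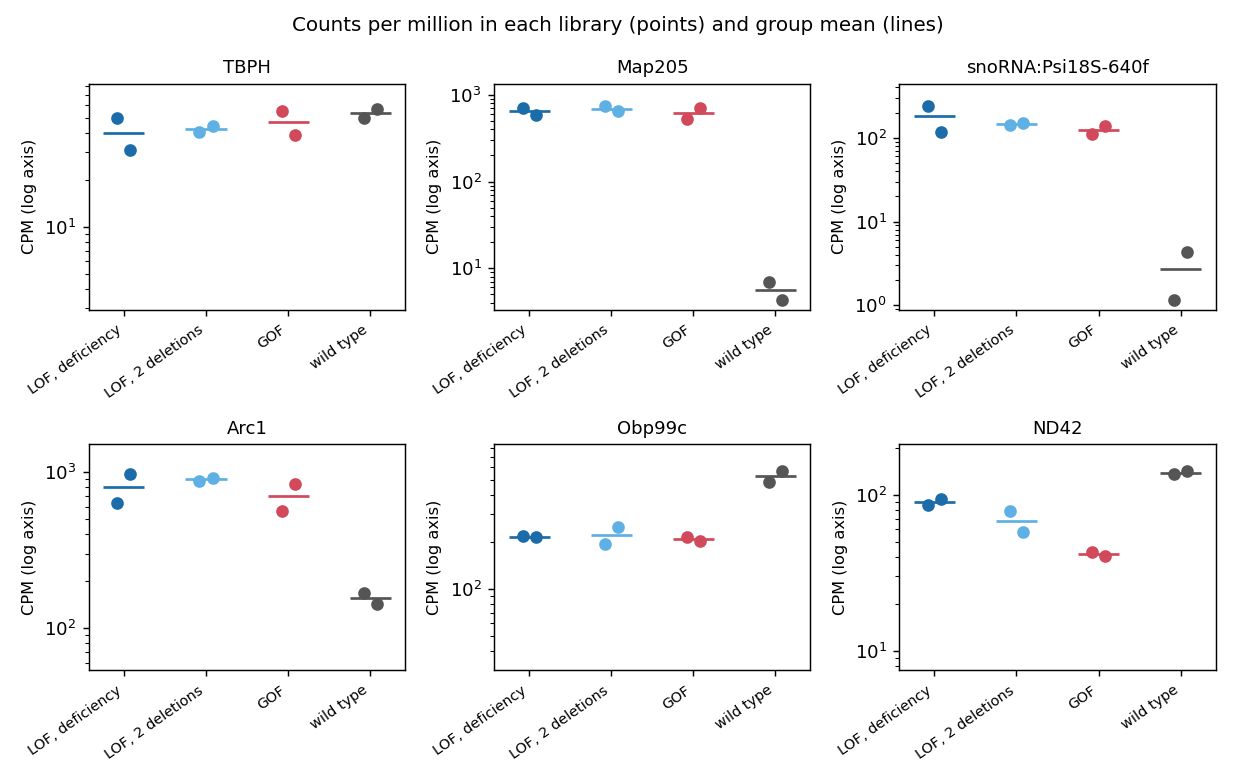
CPM on a log axis for TBPH, Map205, snoRNA:Psi18S-640f, Arc1, Obp99c and ND42 in each of the 8 libraries. Points are libraries and lines are the means of 2 libraries; TBPH overlaps between groups, while Map205 is at 5.61 CPM on average in wild type and at 612 to 695 CPM in the other groups.

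Loss of function against wild type asks which transcripts differ when both loss-of-function genotypes are averaged. Map205, which encodes a microtubule-associated protein, was at 672 ± 66.6 CPM in the loss-of-function libraries (SD, n = 4) and at 5.61 ± 1.88 in wild type (SD, n = 2), a log2 fold of 6.84 (SE 0.30, adjusted p = 2e-07, edgeR). Arc1, a neuronal gene whose protein forms capsid-like particles, rose from 169 and 143 CPM in the wild-type libraries to 854 ± 149 (log2 fold 2.45, SE 0.24, adjusted p = 0.00082). Nuclear genes for oxidative phosphorylation, muscle genes and mitochondrial ribosomal protein genes were lower as lists, at adjusted p = 0.35, 0.69 and 0.061 with an estimated correlation. Ecdysone-response genes and cell cycle genes were higher as lists (adjusted p = 0.35 and 0.58 with it), with no cell cycle gene called. In all, 57 genes were called higher and 146 lower at an adjusted p of 0.05, and 750 and 1096 had an unadjusted p under 0.05.

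Among the steepest rises were 2 snoRNA genes whose products guide pseudouridylation of 18S ribosomal RNA. snoRNA:Psi18S-640f was at 163 ± 54.7 CPM against 2.72 ± 2.21 in wild type (log2 fold 5.91, SE 0.51, adjusted p = 0.00082). snoRNA:Psi18S-525i had 135 counts over the 4 libraries and 1 count over both wild-type libraries, a ratio of 50.3 with a 95% exact counting interval of 8.87 to 2000. A further copy, snoRNA:Psi18S-525c, fell from 133 ± 20.6 to 28.3 ± 9.51 CPM (log2 fold -2.23, adjusted p = 0.015). These genes have near-identical copies, and how reads matching several copies were counted is not given in the sources used here, so the values of single copies are uncertain. CG4151 was at 395 ± 311 CPM against 8.06 ± 3.32 (log2 fold 5.29, adjusted p = 0.012). CG33998 had 458 counts against 3, a ratio of 56.9 (exact interval 19.3 to 277), with 339 of the 458 in the deficiency genotype, and was not called in the 2-deletion genotype (adjusted p = 0.12). Its log2 fold was 9.65 without wild-type replicate 1 and 4.78 without replicate 2, and that of snoRNA:Psi18S-525i was 8.06 and 4.68. Cyp6a20, a cytochrome P450 gene, had 54 counts against 0 and was at least 6.7-fold higher, against a floor of 3 counts over both wild-type libraries. Intervals and floors cover counting error only. Apart from snoRNA:Psi18S-525c, given above, the steepest falls were in genes of low level. CG13217 fell by 3.15 on the log2 scale, CG13405 fell by 2.77, ran-like fell by 2.71, CG32161 fell by 2.33, CG9624 fell by 2.25 and CG15172 fell by 2.14, with adjusted p of 0.015 to 0.05 and wild-type means of 17.5 to 27.9 CPM. CG13217 and CG32161 did not pass the test in the deficiency genotype alone (edgeR adjusted p = 0.086 and 0.11). Their log2 folds were -2.91 and -2.34 in that genotype and -3.39 and -2.33 in the 2-deletion genotype. None of the 6 passed the test in the 2-deletion genotype alone. There CG13405, CG9624 and CG15172 had log2 folds of -1.50, -0.715 and -0.851 (adjusted p = 0.21, 0.47 and 0.41), against -4.05, -3.78 and -3.43 in the deficiency genotype, and the fall of CG13405 in loss of function was 4.47 without deficiency replicate 2. CG15021 (4-fold lower, adjusted p = 0.01) and CG18304 (log2 fold -1.25, adjusted p = 0.01) were among the falls shared with gain of function.

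Of the 35 gene lists tested with camera at a preset correlation, 4 were called higher and 7 lower in loss of function. Of 78 tested oxidative phosphorylation genes, 77 had a negative fold and the median log2 fold was -0.81 (camera adjusted p = 1.12e-21). Over all genes 15 of them were called lower, and 49 adjusted over the list alone. CG4169 (now UQCR-C2, a subunit of complex III) fell from 198 ± 1.33 to 88.8 ± 18.3 CPM (log2 fold -1.16, SE 0.18, adjusted p = 0.012). ATPsyn-gamma, a subunit of the ATP synthase, fell from 207 ± 26.2 to 102 ± 22.2 CPM (log2 fold -1.04, SE 0.17, adjusted p = 0.015). With an estimated correlation the list had an adjusted p = 0.35. Mitochondrial ribosomal protein genes had a median of -0.67 over 59 members (adjusted p = 3.79e-09), of which 1 was called lower over all genes and 1 adjusted over the list alone. That member was mRpL37 (log2 fold -1.69, adjusted p = 0.015). With an estimated correlation this list had an adjusted p = 0.061. For genes of glycolysis and the TCA cycle the median was -0.43 over 30 members (adjusted p = 0.000738, and adjusted p = 0.71 with an estimated correlation), 2 called lower and 5 adjusted over the list alone. The called members were CG7998 (now Mdh2, mitochondrial malate dehydrogenase, log2 fold -0.96) and Acon (now mAcon1, aconitase, log2 fold -0.86). Cytosolic ribosomal protein genes had a median of -0.22 over 83 members (adjusted p = 0.000423, and adjusted p = 0.78 with an estimated correlation), 2 called lower and 4 adjusted over the list alone. RpLP2 (log2 fold -0.99) and RpL30 (log2 fold -0.80) were called.

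Muscle genes had a median of -0.96 over 31 members, 30 of them negative (camera adjusted p = 8.32e-10, and adjusted p = 0.69 with an estimated correlation). Of these, 3 were called lower over all genes and 21 adjusted over the list alone. Mlp84B, a muscle LIM protein gene, fell from 134 ± 0.959 to 64 ± 24.7 CPM (log2 fold -1.13, adjusted p = 0.025). Argk (now Argk1), the arginine kinase gene, fell from 1850 ± 233 to 1060 ± 110 CPM (log2 fold -0.81, adjusted p = 0.033). Phototransduction genes had a median of -0.54 over 26 members (adjusted p = 0.0372, and adjusted p = 0.74 with an estimated correlation), with 2 called lower, and 6 lower and 1 higher adjusted over the list alone. The called genes were eys, which is needed for the space between photoreceptor rhabdomeres (log2 fold -0.98, adjusted p = 0.036), and ninaD, a carotenoid receptor gene (log2 fold -1.88, adjusted p = 0.049). Chemosensory genes had a median of -0.49 over 19 members (adjusted p = 0.0383, and adjusted p = 0.37 with an estimated correlation), 2 called lower and 5 adjusted over the list alone. Both called members encode odorant-binding proteins, Obp99c (525 ± 61.7 to 219 ± 21.9 CPM, log2 fold -1.26, SE 0.15, adjusted p = 0.0043) and Obp99b (log2 fold -0.96, adjusted p = 0.049). By genotype, Obp99b was called in the 2-deletion genotype (log2 fold -1.43, edgeR adjusted p = 0.04). It was not called in the deficiency genotype (log2 fold -0.49, edgeR adjusted p = 0.38).

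Ecdysone-response genes had a median of 0.41 over 43 members, 33 of them positive (camera adjusted p = 9.41e-07, and adjusted p = 0.35 with an estimated correlation). Over all genes 2 were called higher, and 15 adjusted over the list alone. Eig71Eg, an ecdysone-induced gene of a multigene cluster, rose from 4.19 ± 3.9 to 172 ± 145 CPM (log2 fold 4.88, SE 0.58, adjusted p = 0.01). Its log2 fold ranged from 4.27 to 6.45 with 1 library left out. Cyp18a1, whose enzyme inactivates ecdysteroids, rose from 21.1 ± 0.426 to 58 ± 7.45 CPM (log2 fold 1.45, SE 0.29, adjusted p = 0.032). Cell cycle and neuroblast genes had a median of 0.53 over 30 members (adjusted p = 1.4e-05, and adjusted p = 0.58 with an estimated correlation). None of these passed the edgeR test over all genes or adjusted over the list alone. Humoral immunity genes had a median of 0.29 over 36 members (adjusted p = 0.0203, and adjusted p = 0.35 with an estimated correlation), with 0 called over all genes, and 4 higher and 2 lower adjusted over the list alone. The 5 tested members of the salivary glue and gut list were digestive protease genes of the Jonah family and Sgs7. Their median was 3.19, or 2.03 with Jon65Ai at its bound, since it had no count in wild type (adjusted p = 0.00649, and adjusted p = 0.58 with an estimated correlation). None of the 5 was called over all genes or adjusted over the list alone.

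These counts changed with the library left out. Where a group that is compared is left with 1 library, the test also has less power. Without wild-type replicate 1 or 2 there were 4 and 4 genes called higher and 4 and 2 lower, without 2-deletion replicate 1 or 2 there were 23 and 13 higher and 30 and 19 lower, and without gain-of-function replicate 1 or 2 there were 199 and 186 higher and 494 and 498 lower. Of the 31 named genes that were called, Map205, snoRNA:Psi18S-640f and Arc1 stayed called without each of the 8 libraries, and the other 28 lost the call without at least 1, at adjusted p up to 0.363. An adjusted p of 0.01 left 5 higher and 3 lower, limma-voom 17 and 67, a filter of 50 counts 22 and 79, and both genotypes as 1 group 12 and 22.

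Gain of function against wild type asks which transcripts differ when, by the labels, the fly protein is expressed in excess. In the libraries labelled gain of function, Map205 was at 612 ± 123 CPM against 5.61 ± 1.88 in wild type (SD, n = 2 each), a log2 fold of 6.71 (SE 0.31, adjusted p = 3.6e-07, edgeR). Genes for muscle contraction, oxidative phosphorylation and phototransduction were lower as lists, at adjusted p = 0.37, 0.34 and 0.37 with an estimated correlation. Cuticle protein genes moved both ways. Transcripts of the ion channel genes para and slo fell. In all, 85 genes were called higher and 203 lower, and 791 and 1015 had an unadjusted p under 0.05. TBPH itself was not called, as given above.

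snoRNA:Psi18S-640f was at 125 ± 19.5 CPM (log2 fold 5.54, SE 0.55, adjusted p = 0.0039), and CG4151 was at 267 ± 74.9 CPM (log2 fold 4.99, SE 0.58, adjusted p = 0.012). Several rises were from 0 or 1 count in wild type. The ratio was 50 for snoRNA:Psi18S-525i (exact interval 8.7 to 2000), 35.8 for CG33093 (6.16 to 1440) and 23.7 for the noncoding RNA gene pncr009:3L (3.98 to 961). Cyp6a20 was at least 4.28-fold higher, against a floor of 3 counts over both wild-type libraries. Arc1 was at 700 ± 190 CPM (log2 fold 2.16, SE 0.26, adjusted p = 0.0046). The steepest falls included Cpr76Bb, a cuticle protein gene (53.4 ± 13.4 to 2.31 ± 3.27 CPM, log2 fold -4.53, SE 0.69, adjusted p = 0.012), and CG13071 (128 ± 1.73 to 8.15 ± 8.09 CPM, log2 fold -4.01, SE 0.47, adjusted p = 0.0051). Acp1, an adult cuticle protein gene (log2 fold -3.61, adjusted p = 0.037), and CG13217 (log2 fold -3.85, adjusted p = 0.032) also fell. The size of these falls depended on the library left out, at -3.48 and -8.73 for Cpr76Bb, -3.19 and -5.65 for CG13071, -2.57 and -7.51 for Acp1 and -2.80 and -7.75 for CG13217 without gain-of-function replicate 1 and 2. CG14259 had 1 count against 30 in wild type and was lower by a ratio of 44.4 (exact interval 7.38 to 1810). se, which encodes an enzyme of the red eye pigment pathway, had 2 counts against 31 (ratio 22.9, interval 5.84 to 198), and CG7203 had 2 against 26 (ratio 19.2, interval 4.82 to 167). Log2 folds were -7.30 and -3.53 for se and -7.25 and -4.38 for CG14259 without gain-of-function replicate 1 and 2, and 8.06 and 4.67 for snoRNA:Psi18S-525i, 7.56 and 4.18 for CG33093 and 6.97 and 3.59 for pncr009:3L without wild-type replicate 1 and 2.

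Of the 35 lists, 5 were called higher and 11 lower with the preset correlation. Muscle genes had a median log2 fold of -1.68 over 31 members, 30 of them negative (camera adjusted p = 6.22e-20, and adjusted p = 0.37 with an estimated correlation). They differed by a median of 1.02 between the gain-of-function libraries, lower in replicate 1, and the median log2 fold was -1.23 without replicate 1 and -2.58 without replicate 2. Over all genes 17 were called lower, and 28 adjusted over the list alone. Mlp84B fell to 38.1 ± 10.3 CPM (log2 fold -1.81, SE 0.26, adjusted p = 0.0074), and Ca-P60A (now SERCA, the calcium pump of the sarcoplasmic reticulum) fell from 1140 ± 281 to 437 ± 64.9 CPM (log2 fold -1.39, SE 0.21, adjusted p = 0.01). Of 78 oxidative phosphorylation genes, 77 were negative, with a median of -1.22 (adjusted p = 5.93e-31, and adjusted p = 0.34 with an estimated correlation), 35 called lower and 66 adjusted over the list alone. ND42 (now ND-42, a subunit of complex I) fell from 138 ± 4.28 to 41.8 ± 1.62 CPM (log2 fold -1.72, SE 0.23, adjusted p = 0.0067). CG3731 (now UQCR-C1) fell by 1.36 on the log2 scale (adjusted p = 0.0097). Mitochondrial ribosomal protein genes had a median of -0.88 over 59 members (adjusted p = 1.51e-11). This was the 1 list that stayed called with an estimated correlation (adjusted p = 0.038), with 1 gene called lower, mRpL37 (log2 fold -2.08), and 6 adjusted over the list alone. Glycolysis and TCA cycle genes had a median of -0.72 over 30 members (adjusted p = 1.41e-07, and adjusted p = 0.37 with an estimated correlation), 7 called lower and 18 adjusted over the list alone. Among these were Acon (log2 fold -1.34) and CG7998 (log2 fold -1.14). Cytosolic ribosomal protein genes had a median of -0.32 over 83 members (adjusted p = 3.75e-06, and adjusted p = 0.5 with an estimated correlation), 4 called lower and 11 adjusted over the list alone, RpLP2 (log2 fold -1.10) and RpL30 (log2 fold -0.99) among them.

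Phototransduction genes had a median of -0.98 over 26 members (camera adjusted p = 8.7e-06, and adjusted p = 0.37 with an estimated correlation), with 5 called lower, and 13 lower and 1 higher adjusted over the list alone. inaC, the eye protein kinase C gene, fell from 77 ± 22 to 18.2 ± 1.69 CPM (log2 fold -2.08, SE 0.33, adjusted p = 0.012), and eys fell to 82.2 ± 30.2 CPM (log2 fold -1.64, SE 0.24, adjusted p = 0.0097). Ion channel and receptor genes had a median of -0.35 over 50 members (adjusted p = 0.00379, and adjusted p = 0.49 with an estimated correlation), 3 called lower and 3 adjusted over the list alone. slo, a calcium-activated potassium channel gene, fell from 252 ± 3.91 to 111 ± 8.42 CPM (log2 fold -1.19, SE 0.18, adjusted p = 0.0099). para, the voltage-gated sodium channel gene, fell from 120 ± 4.71 to 49.1 ± 6.39 CPM (log2 fold -1.30, SE 0.21, adjusted p = 0.012). Neurotransmitter system genes had a median of -0.60 over 18 members (adjusted p = 0.0171, and adjusted p = 0.42 with an estimated correlation). The 1 member called, over all genes and adjusted over the list alone, was CG1732 (now Gat, a GABA transporter that glia express, log2 fold -1.86, adjusted p = 0.01). Synaptic release genes had a median of -0.20 over 30 members (adjusted p = 0.0168, and adjusted p = 0.37 with an estimated correlation), with CG10617 (now Syt12) the 1 member called over all genes and adjusted over the list alone (log2 fold -1.39, adjusted p = 0.023). Chemosensory genes had a median of -0.57 over 19 members (adjusted p = 0.0222, and adjusted p = 0.34 with an estimated correlation), 2 called lower and 6 adjusted over the list alone. These included the odorant receptor gene Or47a (62.7 ± 16 to 7.58 ± 4.98 CPM, log2 fold -3.07, adjusted p = 0.0067) and Obp99c (log2 fold -1.34, adjusted p = 0.0067).

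Cuticle protein genes had a median of -0.77 over 65 members, 41 negative and 24 positive (camera adjusted p = 0.00182, and adjusted p = 0.69 with an estimated correlation). Over all genes 5 were called lower and 2 higher, and 14 and 4 adjusted over the list alone. Besides Cpr76Bb and Acp1, Cpr62Bb fell (log2 fold -1.84, adjusted p = 0.031). The 2 called higher, Cpr78E (log2 fold 1.53) and Edg91 (log2 fold 1.98), are named after their values were seen. Ecdysone-response genes had a median of 0.38 over 43 members (adjusted p = 9.96e-05, and adjusted p = 0.34 with an estimated correlation), with 3 called higher, and 10 higher and 1 lower adjusted over the list alone. Eig71Eg was at 77.7 ± 10.5 CPM (log2 fold 4.09, SE 0.63, adjusted p = 0.02) and Cyp18a1 at 66.9 ± 20.1 CPM (log2 fold 1.66, SE 0.31, adjusted p = 0.02). With 1 library left out, the log2 fold of Eig71Eg ranged from 3.49 to 5.67. Cyp18a1 was also the 1 called member, over all genes and adjusted over the list alone, of the ecdysteroid synthesis list, whose median was 0.37 over 11 members (adjusted p = 0.0373, and adjusted p = 0.37 with an estimated correlation). Its enzyme inactivates ecdysteroids and does not make them. Humoral immunity genes had a median of 0.41 over 36 members (adjusted p = 0.00755, and adjusted p = 0.34 with an estimated correlation), 1 called higher and 3 adjusted over the list alone. The called gene was Dpt, which encodes the antibacterial peptide diptericin (15.4 ± 0.476 to 62.3 ± 25.4 CPM, log2 fold 2.02, adjusted p = 0.023). Cell cycle and neuroblast genes had a median of 0.72 over 30 members (adjusted p = 1.41e-07, and adjusted p = 0.37 with an estimated correlation), 0 called over all genes and 4 adjusted over the list alone. Apoptosis genes had a median of 0.36 over 18 members (adjusted p = 0.00863, and adjusted p = 0.42 with an estimated correlation), with none called either way.

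Without wild-type replicate 1 or 2 there were 7 and 3 genes called higher and 35 and 0 lower (1343 and 1284 genes in all with an unadjusted p under 0.05); without gain-of-function replicate 2 there were 200 and 457, without deficiency replicate 1 or 2 129 and 131 called higher, and without 2-deletion replicate 1 or 2 45 and 52 higher and 102 and 110 lower. Of the 35 named genes that were called, Map205 and snoRNA:Psi18S-640f stayed called without each library, and the other 33 lost the call without at least 1, at adjusted p up to 0.261. Arc1, CG15021 and CG18304, named for the calls shared with loss of function, are not among these 35. An adjusted p of 0.01 left 6 higher and 15 lower, and the gain-of-function and wild-type libraries alone 39 and 71.

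Of the 35 lists, 18 were called in neither comparison. Median log2 folds in loss and gain of function were 0.02 and -0.23 for pan-neuronal genes, 0.00 and 0.09 for glial genes, -0.02 and -0.11 for microtubule and axonal genes, and -0.11 and 0.02 for other neuropeptides. They were 0.20 and 0.08 for axon guidance and adhesion, 0.17 and 0.16 for RNA-binding and splicing factors, and 0.18 and 0.18 for clock genes. Genes reported elsewhere as fly TDP-43 targets had medians of -0.02 and -0.29 over 10 tested members (adjusted p = 0.9 and 0.221). For eye pigment genes the medians were 0.08 and 0.06, for cuticle tanning and chitin genes 0.05 and 0.03, for fat body storage genes 0.07 and 0.07, and for haemocyte genes 0.14 and 0.35. Heat shock and chaperone genes had 0.14 and 0.07, redox and detoxification genes -0.02 and 0.00, proteasome genes -0.05 and 0.05, autophagy and lysosome genes 0.10 and 0.21, histones -0.03 and -0.12, and sex markers 0.01 and 0.09. The salivary glue and gut list was not called in gain of function (median 1.02, adjusted p = 0.244). Of the ecdysis peptide list only rk, Eh and CcapR could be tested, and none of the mitochondrial genome list, so neither list had a set test. In loss and gain of function the log2 folds were 0.38 and 0.35 for rk, -1.70 and -0.01 for Eh, and -0.90 and -1.43 for CcapR, at adjusted p of 0.14 to 0.99.

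**Figure D2:**
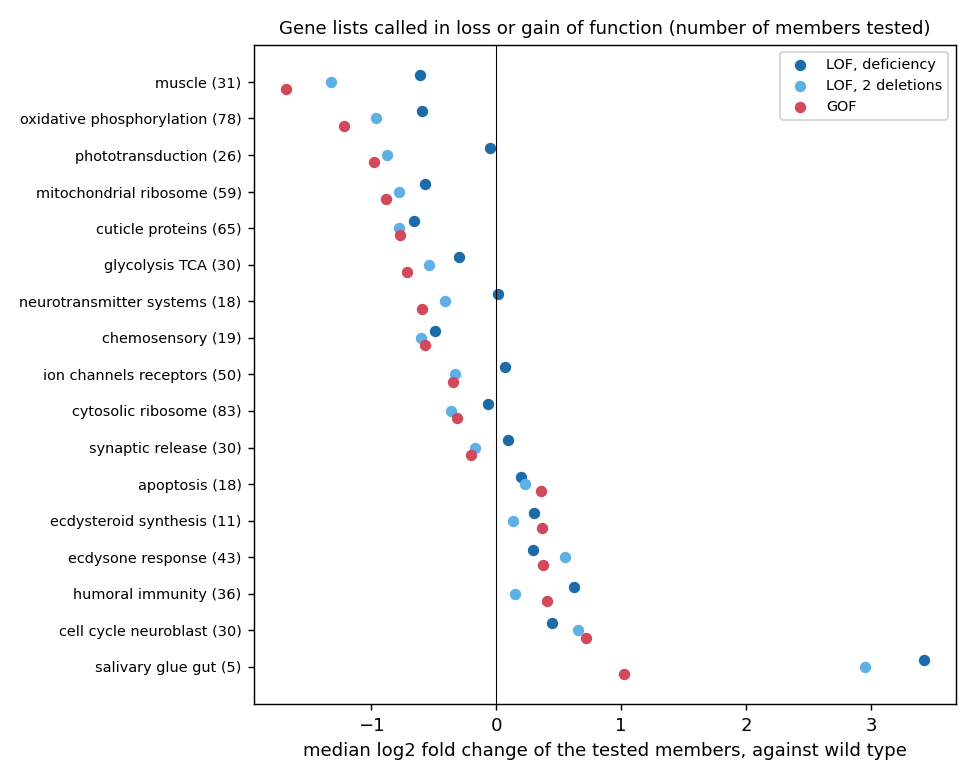
Median log2 fold change against wild type of the tested members (number in parentheses) of the 17 gene lists called in loss or gain of function, for the deficiency genotype, the 2-deletion genotype and gain of function. The muscle median is -0.61, -1.32 and -1.68 and the oxidative phosphorylation median -0.60, -0.96 and -1.22 in that order, and most of these calls do not hold with an estimated correlation.

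The genes called in loss and in gain of function were compared to see whether both conditions changed shared genes. Of 203 and 288 called genes, 35 were called higher in both, 84 lower in both and 0 in opposite directions. Map205, snoRNA:Psi18S-640f and Arc1 had the smallest p-values among the shared rises, and Obp99c, CG15021 and CG18304 among the shared falls. CG15021 was at 17.8 ± 2.26 CPM in loss of function (SD, n = 4), 6.59 ± 2.44 in gain of function and 71.8 ± 19.7 in wild type. Independent lists would share 0.524 higher and 3.2 lower genes. In 40 simulations of unchanged groups against shared wild-type libraries, at most 1 higher and 2 lower genes were shared. Few genes are called in unchanged groups, so these low counts are no measure for lists of 203 and 288 genes. The simulations also held no difference particular to the wild-type libraries. Across genes, which are not independent replicates, the correlation of the log2 folds was 0.845 against a simulated mean of 0.617, and the covariance was 0.5 against 0.123, a difference of 0.377. Both comparisons use the same 2 wild-type libraries, which cannot be split, so part of the excess may come from them. The shared counts fell to 4 higher and 4 lower without wild-type replicate 1, 3 and 0 without replicate 2, 13 and 21 without 2-deletion replicate 1 and 13 and 17 without its replicate 2; they were 70 higher without gain-of-function replicate 1, 66 higher and 285 lower without its replicate 2, and 1 gene was called in opposite directions without deficiency replicate 2.

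**Figure D3:**
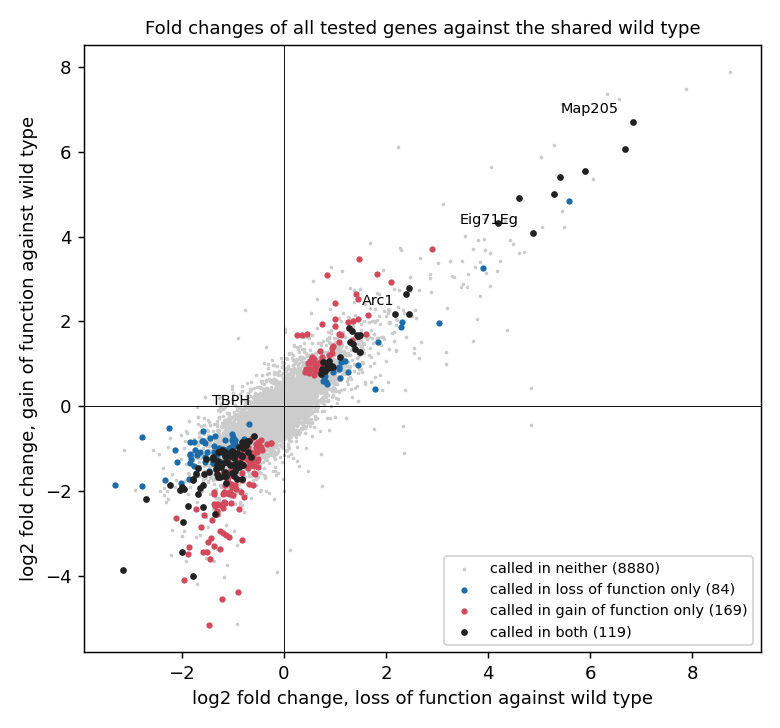
Log2 fold change against wild type of the 9252 tested genes in loss of function (x axis) and gain of function (y axis), coloured by the comparison in which each was called. The 119 genes called in both have the same sign on both axes; both axes share the wild-type libraries, and fitted values of genes with no wild-type count depend on the prior count.

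Deficiency genotype against wild type takes the first loss-of-function genotype by itself. Map205 was at 648 ± 77.9 CPM (SD, n = 2; log2 fold 6.79, SE 0.31, adjusted p = 3.2e-07, edgeR). Cyp6a20 was at least 10.2-fold higher than the floor of 3 counts over both wild-type libraries. The ratio to wild type was 102 for CG33998 (339 counts against 3, exact interval 34.5 to 495) and 98.1 for CG42460 (109 against 1, 17.2 to 3910). With all libraries their log2 folds were 6.61 and 6.35. With 1 library left out, the log2 fold ranged from 5.76 to 10.7 for CG33998, the highest without wild-type replicate 1. For CG42460 it ranged from 5.62, without wild-type replicate 2, to 9. CG31787 had 0 counts against 17 and was at least 6.3-fold lower, with the floor taken over both libraries of the genotype. The ratios were 18.3 for CG13405 (2 counts against 33, interval 4.69 to 158), 15 for CG9624 (2 against 27, 3.77 to 130) and 11.5 for CG15172 (3 against 31, 3.58 to 58.7), all lower. With 1 library left out, the log2 fold of CG13405 ranged from -7.43 to -3.17, against -4.05 with all libraries. In all, 52 genes were called higher and 103 lower, and 676 and 940 had an unadjusted p under 0.05.

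Lists called higher were ecdysone response (median 0.30, 4 of 43 called and 13 adjusted over the list alone), humoral immunity (median 0.63, 0 of 36 called and 3 adjusted over the list alone), cell cycle and neuroblast genes (median 0.44, 0 of 30 either way) and the 5 salivary glue and gut genes (median 3.42, 0 called and 1 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.3, 0.26, 0.68 and 0.53. Lists called lower were oxidative phosphorylation (median -0.60, 1 of 78 called and 12 adjusted over the list alone), mitochondrial ribosomal proteins (median -0.57, 1 of 59 called and 1 adjusted over the list alone) and muscle (median -0.61, 0 of 31 either way), at adjusted p = 0.6, 0.15 and 0.8 with an estimated correlation. There were 6 higher and 3 lower calls without wild-type replicate 1 and 4 and 0 without its replicate 2 (1227 genes with an unadjusted p under 0.05), and 39, 58, 49 and 53 lower calls without deficiency replicate 1 or 2 or 2-deletion replicate 1 or 2. Without gain-of-function replicate 1 or 2 there were 152 and 157 higher and 351 and 337 lower, limma-voom called 2 and 6, and of the 8 named genes only Map205 stayed called without each library, the other 7 reaching adjusted p up to 0.236.

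2-deletion genotype against wild type takes the second genotype by itself. Map205 was at 695 ± 70.7 CPM (SD, n = 2; log2 fold 6.89, SE 0.31, adjusted p = 2.6e-07, edgeR) and snoRNA:Psi18S-640f at 146 ± 5.41 CPM (log2 fold 5.76, SE 0.54, adjusted p = 0.0016). The ratio to wild type was 36.9 for snoRNA:Psi18S-525i (58 counts against 1, exact interval 6.36 to 1480) and 26.7 for CG33093 (42 against 1, 4.54 to 1080). With 1 library left out, their log2 folds ranged from 4.22 to 7.6 and from 3.76 to 7.15. CG30104 (now NT5E-2) fell from 105 ± 18.8 to 16.7 ± 0.583 CPM (log2 fold -2.65, adjusted p = 0.021), CG33299 fell from 44.9 ± 23.2 to 4.93 ± 1.49 CPM (log2 fold -3.19, adjusted p = 0.042), and CG4288 (now MFS9) fell from 30.5 ± 10.8 to 4.5 ± 0.887 CPM (log2 fold -2.75, adjusted p = 0.037). CG7203 had 3 counts against 26, a ratio of 13.6 (interval 4.18 to 70.4) in the lower direction. In all, 23 genes were called higher and 54 lower, and 669 and 793 had an unadjusted p under 0.05.

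Lists called higher were ecdysone response (median 0.55, 1 of 43 called and 8 adjusted over the list alone), cell cycle and neuroblast genes (median 0.66, 0 of 30 called and 1 adjusted over the list alone) and heat shock and chaperone genes (median 0.28, 1 of 28 called, and 9 higher and 2 lower adjusted over the list alone). Their adjusted p with an estimated correlation was 0.25, 0.51 and 0.51. Muscle genes (median -1.32, 2 of 31 called lower and 23 adjusted over the list alone) and oxidative phosphorylation genes (median -0.96, 12 of 78 and 58) were lower as lists, at adjusted p = 0.51 and 0.25 with an estimated correlation. Phototransduction (median -0.87, 1 of 26 called lower, and 9 lower and 1 higher adjusted over the list alone), glycolysis and the TCA cycle (median -0.54, 2 of 30 called lower, and 14 lower and 1 higher) and cytosolic ribosomal proteins (median -0.36, 2 of 83 called lower and 6 adjusted over the list alone) each had an adjusted p = 0.51 with an estimated correlation. The mitochondrial ribosomal protein list (median -0.78, 1 of 59 called lower and 1 adjusted over the list alone) stayed called with it (adjusted p = 0.04). Chemosensory genes (median -0.60, 2 of 19 called lower and 5 adjusted over the list alone), ion channels and receptors (median -0.33, 1 of 50 called lower, and 3 lower and 1 higher) and neurotransmitter systems (median -0.41, 0 of 18 called and 2 lower) had an adjusted p = 0.25, 0.53 and 0.51 with it. Cuticle proteins (median -0.78) and the proteasome (median -0.26) had no called member of 65 and 38 either way, at adjusted p = 0.79 and 0.53 with an estimated correlation. There were 3 higher and 3 lower calls without wild-type replicate 1, 3 and 1 without its replicate 2, 4 and 0 without 2-deletion replicate 1 and 3 and 0 without its replicate 2, against 128 and 263 without gain-of-function replicate 1 and 117 and 288 without its replicate 2. Without deficiency replicate 1 or 2 there were 43 and 45 higher and, without replicate 2, 108 lower; limma-voom called 2 and 12, and of the 8 named genes Map205 and snoRNA:Psi18S-640f stayed called without each library, the other 6 reaching adjusted p up to 0.294.

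Both loss-of-function genotypes shared 10 genes called higher, 15 called lower and 0 in opposite directions. Independent lists would share 0.129 and 0.601. Simulated unchanged groups shared at most 1 in either direction, but few genes are called in such groups, so this is no measure for the lists found here. Map205 was among the shared rises. The correlation of log2 folds across genes was 0.739 against a simulated 0.535, and the covariance 0.449 against 0.123, a difference of 0.326; the genotypes share the wild-type libraries and the delta142 allele. The shared counts were 3 higher and 3 lower without wild-type replicate 1, 3 and 0 without its replicate 2, 4 and 0 without 2-deletion replicate 1, 3 and 0 without its replicate 2, 16 and 4 without deficiency replicate 1, 19 and 9 without its replicate 2, and 58 and 96 or 57 and 97 without gain-of-function replicate 1 or 2.

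Deficiency genotype against 2-deletion genotype tests the difference between the loss-of-function genotypes, in which wild type cancels. No gene passed the edgeR test (0 higher and 0 lower, 377 and 492 with an unadjusted p under 0.05). The smallest adjusted p was 0.0628, for CG13360, at 15 ± 2.6 CPM in the deficiency genotype and 72.5 ± 5.03 in the 2-deletion genotype (SD, n = 2 each). DESeq2 called 3 genes higher and 3 lower, among them the heat shock gene Hsp68, which was lower in the deficiency genotype at 273 ± 122 against 1240 ± 197 CPM. limma-voom called 0. Genes were called without deficiency replicate 1 (12 higher and 12 lower), without its replicate 2 (5 and 1), without 2-deletion replicate 2 (1 and 0), and without gain-of-function replicate 1 (3 and 12) or 2 (1 and 6); CG13360 and Hsp68 are named after their values were seen.

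As lists, muscle genes were higher in the deficiency genotype (median difference 0.81, 31 of 31 positive, camera adjusted p = 1.49e-10, and adjusted p = 0.46 with an estimated correlation), and so were phototransduction genes (median 0.53, 22 of 26), ion channels and receptors (0.38, 43 of 50), neurotransmitter systems (0.49, 16 of 18) and synaptic release genes (0.25, 27 of 30), the last 4 at adjusted p = 0.4 with it. Oxidative phosphorylation (median 0.37, 66 of 78 positive), cytosolic ribosomal protein (0.27, 77 of 83), glycolysis and TCA cycle (0.29, 25 of 30), proteasome (0.19, 30 of 38), humoral immunity (0.41, 29 of 36), cuticle protein (0.40, 49 of 65) and salivary glue and gut genes (1.20, 5 of 5) were higher too. Heat shock and chaperone genes were lower (median -0.26, 23 of 28 negative). With an estimated correlation none of the 13 lists was called, at adjusted p of 0.4 to 0.72. Over all genes edgeR called none of these members, while the DESeq2 Wald test called Hsp68 and DnaJ-1, the latter named after its values were seen; adjusted over the list alone, 3 neurotransmitter genes, 1 phototransduction gene and 1 salivary gene were called higher and 8 heat shock genes lower.

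Loss of function against gain of function tests the difference between the loss and gain effects, and wild type cancels here too. No gene passed the edgeR test (0 higher and 0 lower, 274 and 233 with an unadjusted p under 0.05). The smallest adjusted p was 0.575, for CS-2, a chitin synthase gene. It follows that none of the 372 genes called in loss or gain of function against wild type was called between loss and gain. This is no separate result, and differences of moderate size can be missed. Map205 differed by a log2 value of 0.13 (SE 0.17), and TBPH by -0.20, with a 95% interval of -0.76 to 0.36. DESeq2 called 1 gene higher, CG14961, and 1 lower, snoRNA:Me28S-A774b, both named after their values were seen, and limma-voom called 0. Without gain-of-function replicate 2 there were 75 genes called higher and 34 lower; without 2-deletion replicate 1 there were 2 higher, without deficiency replicate 2 there were 2 lower, and without gain-of-function replicate 1 there was 1 lower.

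As lists, muscle genes were higher in loss than in gain of function (median 0.83, 31 of 31 positive, camera adjusted p = 1.53e-19, and adjusted p = 0.49 with an estimated correlation), as were oxidative phosphorylation genes (0.41, 69 of 78), phototransduction genes (0.43, 22 of 26), glycolysis and TCA cycle genes (0.30, 27 of 30) and mitochondrial ribosomal protein genes (0.19, 43 of 59), each at adjusted p = 0.49 with it. For muscle genes the gain-of-function replicates differed by a median of 1.02, more than loss and gain did, and the median was 0.37 without replicate 1 and 1.60 without replicate 2. Neuronal lists were higher too, with medians of 0.19 for synaptic release, 0.29 for neurotransmitter systems, 0.29 for ion channels and receptors and 0.26 for pan-neuronal genes, each at adjusted p = 0.49 with an estimated correlation. Cuticle protein genes (median 0.12, 39 of 65 positive) and cytosolic ribosomal protein genes (0.11, 62 of 83) were called higher, and proteasome genes (median -0.12) and cell cycle and neuroblast genes (median -0.25) lower. With an estimated correlation none of the 13 lists was called, at adjusted p of 0.49 to 0.65. Over all genes edgeR called no member; adjusted over the list alone, 1 neurotransmitter gene, 2 phototransduction genes and 1 cuticle gene were called higher and 1 cuticle gene lower. The median turned without gain-of-function replicate 1 to -0.21 for cuticle proteins and to 0.02 for cell cycle genes, and without gain-of-function replicate 2 to -0.06 for cytosolic ribosomal proteins.

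Genes near TBPH were examined because the deficiency removes 1 copy of an unstated stretch around the gene. Of the 40 annotated genes on each side, 50 were tested. Their median log2 fold was -0.30 in the deficiency genotype, -0.18 in the 2-deletion genotype and -0.15 in gain of function against wild type. In the deficiency genotype 39 of the 50 genes were lower, and 3.97% of 10000 random runs of neighbouring genes had a median as low, against 11.5% for the 2-deletion genotype, 15.2% for gain of function, 6.14% for loss of function and 3.27% for loss against gain (median -0.14). The difference between the loss-of-function genotypes over these genes had a median of -0.06, against a spread of 0.0571 between replicates, at the 21.5th percentile of random runs. It was -0.15 without deficiency replicate 1, 0.02 without its replicate 2 and -0.13 without gain-of-function replicate 1. In each comparison with wild type 1 of the 50 genes was called, and 0 in the other comparisons. In loss of function, gain of function and the 2-deletion genotype this was the muscle gene Ca-P60A. Between the genotypes 29 were lower in the deficiency genotype and 21 higher. CG5539, named after its values were seen, had the largest difference (-2.88, SE 0.59).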

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

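The camera test between the loss-of-function genotypes, the search for a library far from the others and the test of differences between pools of heads were chosen before the results were seen, and the other tests in this part only after. The lists over which the test of pools was run were picked after camera had called them lower. In all, 63 results (the 57 named genes and measures of the libraries) were examined in the 4 loss-of-function libraries for a library far from the others. Of these, 0 exceeded the 95% critical value of Dixon's test, which chance exceeds in about 1 of 20. The 4 libraries are of different genotypes, so where the genotypes differ a single far library can go unseen. Gain-of-function and wild-type libraries were not examined in this way.

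A difference between the loss-of-function genotypes, tested by camera with a preset correlation on the deficiency minus the 2-deletion genotype, was called for 13 lists. The median log2 difference was 0.811 for muscle, 0.531 for phototransduction, 0.494 for neurotransmitter systems, 0.383 for ion channels and receptors, 0.252 for synaptic release, 0.405 for humoral immunity and 0.4 for cuticle proteins. It was 0.373 for oxidative phosphorylation, 0.29 for glycolysis and the TCA cycle, 0.27 for cytosolic ribosomal proteins, 0.186 for the proteasome, 1.2 for salivary glue and gut genes and -0.259 for heat shock and chaperone genes. With an estimated correlation none was called (adjusted p of 0.4 to 0.72).

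Map205, and the snoRNA genes Psi18S-640f and Psi18S-525i, which neighbour each other, were almost without counts in wild type. The counts argued against low depth as a cause, since 1020 counts of Map205 would be expected over both wild-type libraries at the mean level of the other 6. A variant of the wild-type stock could account for Map205, since loss and gain of function differed by only 0.133 (SE 0.17) and the genes adjacent to Map205, mod and krz, had log2 folds of -0.258 and 0.239 in loss of function, neither called; mod fell by 0.855 in gain of function (adjusted p = 0.0416). For reads assigned to other snoRNA copies the tests could not tell: all 6 other copies of 640f gained 0.0407 (SE 0.15) of the missing CPM in wild type and the largest single gain was 0.429 (SE 0.207), while the 10 other copies of 525i summed to -17.9 (SE 4.73) and the largest single gain was 3.12 (SE 0.472), the single-copy tests being chosen after the summed ones. An effect shared by loss and gain of function would give the same counts for Map205, so the design does not separate it from the stock.

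The lists of oxidative phosphorylation, muscle and phototransduction genes were lower in both loss and gain of function, at adjusted p of 0.34 to 0.74 with an estimated correlation. In the deficiency genotype alone phototransduction had a median of -0.0505 (12 members positive and 14 negative, camera adjusted p = 0.736), against -0.87 in the 2-deletion genotype. Differences between pools of heads could not be told apart from genotype: replicate differences correlated with the difference from wild type at r = -0.121, -0.205 and 0.117 over 135 genes in gain of function, the deficiency genotype and the 2-deletion genotype, and replicate 2 exceeded replicate 1 by a median of 1.02, 0.447 and 0.0831 for muscle, 0.302, 0.38 and -0.0674 for phototransduction and 0.281, 0.24 and 0.0792 for oxidative phosphorylation in that order. Scaling moves all genes alike, so it cannot by itself set a list apart from all genes. The list medians lay 0.546 to 1.69 below the median of all genes. The nearest was at -0.546 (phototransduction in loss), against -0.265 to 0.205 for 95% of random gene sets of its size. These lists were examined because camera had called them lower than other genes, so this distance is no separate test. The random sets also leave out the correlation within a list. A younger stage could not be told: summed rhodopsin CPM differed from wild type by 0.62 on the log2 scale (SE 0.494) in the deficiency genotype, -1.16 in the 2-deletion genotype and -2.5 in gain of function, while less muscle in the mutant samples and an effect of TBPH on these genes were not tested.

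TBPH did not pass the test in any genotype, and a halving was not excluded in the deficiency genotype (95% interval of -1.1 to 0.267 on the log2 scale). Too few counts to see a doubling in gain of function was argued against, since the 95% interval ended at 0.479 on the log2 scale. Whether loss and gain libraries were swapped could not be told, with a difference of -0.2 between them and an interval that holds 0. Sequence that is still transcribed outside the deleted part, or a transgene without counted sequence, was not tested.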

How the results depend on the processing

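All alternatives were chosen before the data were examined, except the fit of protein-coding genes only, which was chosen after seeing the data. For loss of function against wild type and against gain of function 11 other settings were run, for the other comparisons all of these but both genotypes as 1 group, and each of the 8 libraries was left out in turn; a group left with 1 library is assumed to vary like the others. Most calls were lost when 1 wild-type library was left out. Such a fit leaves wild type with 1 library and has less power by design. Whether anything else contributed was not tested. Of 85 called results on named genes, DESeq2 size factors kept 85, the DESeq2 Wald test kept 57, lost 7 and gave no adjusted p for 21, and limma-voom kept 51 and lost 34. Over all calls the DESeq2 Wald test kept 100 of 203 in loss of function and 164 of 288 in gain of function. Depth limits genes near the floor of 3 counts.

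Leaving out 1 library gave 4 to 199 genes called higher and 2 to 498 lower in loss of function, 3 to 200 and 0 to 457 in gain of function, 4 to 157 and 0 to 351 in the deficiency genotype, and 3 to 128 and 0 to 288 in the 2-deletion genotype. It gave 0 to 12 and 0 to 12 in deficiency against 2-deletion, and 0 to 75 and 0 to 34 in loss against gain. Shared calls were 3 to 70 higher, 0 to 285 lower and 0 to 1 opposite for loss and gain, and 3 to 58 and 0 to 97 for both genotypes.

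An adjusted p of 0.01 gave 5 higher and 3 lower in loss of function, 6 and 15 in gain of function, 8 and 6 in the deficiency genotype and 3 and 0 in the 2-deletion genotype, with fewer genes by construction; it left 5 and 1 shared by loss and gain and 3 and 0 by both genotypes. With no low-count filter there were 116 and 287, 155 higher, 108 and 210, and 63 and 125 in that order, and 2 and 5 in deficiency against 2-deletion. The stricter filter gave 22 and 79 in loss, 53 higher in gain, 12 and 23 in the deficiency genotype and 11 higher in the 2-deletion genotype, with 16 higher shared by loss and gain and 6 and 6 by both genotypes. The DESeq2 Wald test gave 94 lower in loss, 65 lower in the deficiency genotype, 44 higher in the 2-deletion genotype, 3 and 3 in deficiency against 2-deletion, 1 and 1 in loss against gain, and 29 and 8 shared by both genotypes. limma-voom gave 17 and 67, 49 higher, 2 and 6, and 2 and 12. Only the libraries compared gave 176 and 485 in loss, 39 and 71 in gain, 107 and 225 in the deficiency genotype and 248 and 450 in the 2-deletion genotype. Both genotypes as 1 group gave 12 and 22 in loss. Upper-quartile scaling gave 172 lower in the deficiency genotype and 2 lower in deficiency against 2-deletion. Protein-coding genes only gave 37 and 87 in the 2-deletion genotype and 1 lower in deficiency against 2-deletion. For these the cause was not tested.

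Replicate numbers showed no strong pairing of the libraries. Deviations from group means correlated at 0.077 to 0.17 between the mutant groups and at -0.041 to -0.025 between these and wild type. A weak effect that goes with the number in the mutant libraries is left open. With the number as a block there were 43 and 104 calls in the 2-deletion genotype, 1 and 2 in deficiency against 2-deletion, 137 lower shared by loss and gain, 21 higher shared by both genotypes, and 1 list lower in loss against gain.

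Of lists called higher and lower, an estimated correlation left 0 and 0 in loss, 0 and 1 in gain, 0 and 0 in the deficiency genotype, 0 and 1 in the 2-deletion genotype and 0 and 0 in deficiency against 2-deletion and in loss against gain. fry left 1 and 3, 0 and 3, 1 higher, 0 and 3, 0 and 0, and 0 and 0. In loss and gain of function fry called oxidative phosphorylation (adjusted p = 0.0328 and 0.0183), mitochondrial ribosomal proteins (0.00306 and 0.0031) and chemosensory genes (0.00306 and 0.0031) lower. Ecdysone response was called higher by fry in loss only (0.0328 against 0.0556). Muscle (fry adjusted p = 0.156 and 0.0556) and phototransduction (0.217 and 0.0556) were called in neither. Leaving out 1 library gave 3 to 6 and 5 to 7 lists in loss, 3 to 5 and 7 to 11 in gain, 3 to 5 and 2 to 4 in the deficiency genotype, 3 to 5 and 7 to 10 in the 2-deletion genotype, 10 to 15 and 1 to 2 in deficiency against 2-deletion, and 5 to 13 and 1 to 2 in loss against gain. In loss against gain the median ranged from -0.209 (without gain-of-function replicate 1) to 1.41 for cuticle proteins, from -0.0589 (without its replicate 2) to 0.271 for cytosolic ribosomal proteins and from -0.443 to 0.0151 (without its replicate 1) for cell cycle genes, and the cause was not tested.

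Near TBPH, 20 genes on each side gave medians of -0.42 in loss, -0.241 in gain and -0.424 in the deficiency genotype, and 80 gave -0.234 in the deficiency genotype, 0.0111 in deficiency against 2-deletion and 0.00265 in loss against gain. Leaving out 1 library gave -0.447 to -0.207, -0.246 to -0.0162, -0.384 to -0.219, -0.252 to -0.185 for the 2-deletion genotype, -0.15 to 0.0221 for deficiency against 2-deletion and -0.205 to -0.0913 for loss against gain.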

Other observations

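The genes of this part were chosen only after their values were seen, and the test of neighbouring genes was written before. Hsp68, which encodes a heat-inducible chaperone, was at 1240 ± 197 CPM in the 2-deletion genotype, 273 ± 122 in the deficiency genotype, 599 ± 136 in gain of function and 383 ± 28.8 in wild type (SD, n = 2 each). It rose in the 2-deletion genotype against wild type (log2 fold 1.69, SE 0.29, adjusted p = 0.037, edgeR with Benjamini-Hochberg adjustment). Hsf, the heat shock factor gene, was at 243 ± 0.171 and 109 ± 3 CPM in the 2-deletion and deficiency genotypes, Hsp83 at 2270 ± 225 and 1230 ± 89.2, and DnaJ-1 at 672 ± 8.54 and 231 ± 90.8, and none of these passed the edgeR test between the genotypes (adjusted p = 0.29, 0.29 and 0.33). Between the genotypes edgeR called none of the 28 heat shock and chaperone genes over all genes and 8 adjusted over the list alone, the DESeq2 Wald test called Hsp68 and DnaJ-1, and the list had an adjusted p = 0.4 with an estimated correlation.

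Lsd-1 and Lsd-2 encode proteins of lipid droplets. Lsd-1 was at 102 ± 11.1 CPM in wild type and 195 ± 13.2 in gain of function, with log2 folds of 0.97 (SE 0.17, adjusted p = 0.019) and 0.93 (SE 0.19, adjusted p = 0.025) in loss and gain. Lsd-2 had log2 folds of 0.72 (adjusted p = 0.039) and 0.75 (adjusted p = 0.039). Fbp2, a fat body protein gene, fell in loss of function (log2 fold -0.95, adjusted p = 0.049). So did Obp99b (log2 fold -0.96) and v(2)k05816 (now FASN2, log2 fold -1.18), which also fell in gain of function (log2 fold -1.64). Fbp2 and Obp99b were called in the 2-deletion genotype (log2 fold -1.43 each, edgeR adjusted p = 0.037 and 0.04). In the deficiency genotype they were not (log2 folds -0.47 and -0.49, edgeR adjusted p = 0.39 and 0.38). The fat body storage list, which holds all 5 genes, was not called in loss or gain of function (camera adjusted p = 0.9 and 0.93). ple, which encodes tyrosine hydroxylase, was at 1060 ± 496 CPM in the deficiency genotype, 291 ± 210 in the 2-deletion genotype, 195 ± 128 in gain of function and 89 ± 19.6 in wild type, and did not pass the test in any comparison, though it was called between the loss-of-function genotypes with the replicate number as a block. The dosage compensation RNA roX1 was at 776 to 1640 CPM across all 8 libraries and the eye colour gene w at 27.8 to 45.4.

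Stretches of the genome that differ between the wild-type stock and the other stocks might place genes called in both loss and gain of function next to each other. Among the 116 such genes with a place, 2 neighbouring pairs were found, against a median of 4 and a 95th percentile of 8 in 10000 random sets (permutation p = 0.943). The test counts only called genes no more than 2 tested genes apart. It showed no excess of such close pairs. Differences between stocks that are spread along the genome would not place called genes side by side, so the test cannot decide about them.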
